A study of Mus musculus with 13 samples.

How the data were processed

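RNA was measured by sequencing in 13 mouse libraries. The labels name 4 proneural glioblastomas (PN3, PN4, PN5, PN6), 2 normal brains sequenced with them (C2, C5), 4 glioblastomas with AAE codes (AAE6 to AAE9) and 3 normal brains with AAE codes (AAE3, AAE4, AAE5). Per the labels' protocols, tumours were induced with a lentiviral vector that carries PDGFB, a growth factor, and a short hairpin RNA against p53. Normal tissue was trimmed from GFP-positive tumour tissue, RNA was purified on columns with DNase, and libraries were made with a TruSeq RNA kit. The labels give the same strain and vector for all 13 libraries, normal brain included. The design text calls the re-used set mesenchymal without naming its samples; the AAE libraries are that set by elimination.

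Each library has its own file of counts per Ensembl gene, deposited by the authors without normalization. The submitters' processing notes name fastp 0.20.1, STAR 2.7.2a, DESeq2 1.30.1 and the mouse build GRCm38, with no role or order. The counting tool, gene annotation and strand setting are not given in the sources used here, so reads of antisense and overlapping genes cannot be assigned with certainty. The authors also deposited a table of normalized signal for the 6 newer libraries. In it every value equals the library's count divided by a single factor, between 0.991 (C2) and 1.28 (C5), with a relative deviation of at most 4.88e-15. It lists 18691 genes, each with at least 66 counts over all 13 libraries, and every gene it leaves out had at most 65. A further 7 columns of that table were not tied to a sample and were not used.

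Each count file holds 54232 genes, and none of its rows lacks a gene. Symbols and coordinates came from GENCODE release M21 on GRCm38, in which 54165 of the identifiers were found and 67 were not. Library totals ran from 6569547 counts (AAE6) to 18450783 (AAE8). Counting error is therefore small for genes above 10 CPM, and intervals and floors given here cover counting error only. CPM, a gene's counts scaled to the library total, was computed here from the deposited counts with TMM scaling.

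Counts were fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with a mean for each of the 4 groups over all 13 libraries. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19859. The 5 comparisons were set before the data were examined: tumour against labelled normal brain in each cohort, the difference of these effects, the direct contrast of the tumour groups, and the labelled normal brains between cohorts. The quasi-likelihood test with robust estimation was used with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) are the log2 fold change divided by the square root of the test's F. Where a group held 0 counts of a gene, the fold is a lower bound against 3 counts over that group. With 1 to 3 counts it is a ratio with a 95% Poisson interval on those counts alone.

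A set of 33 gene lists (glioblastoma subtypes, cell types, pathways, brain regions) was fixed before the data were examined, as was a list of sex-linked genes for which values alone are given. Each list was tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 33 lists. The same test with an estimated correlation and the rotation test fry stand beside it. None of the 33 lists passed with an estimated correlation in any of the 5 comparisons. In 1 list the name Chi3l1 was read as Chil1, and 20 genes belong to more than 1 list. Another 10 lists of genes of other tissues were written after the values of C2 and C5 had been seen. Single genes named in the comparisons follow a rule fixed beforehand. It takes Pdgfb, Trp53, Nf1, Pdgfra and Pdgfrb in every comparison. It adds up to 3 members of each list with the greatest change among those past the threshold with a group mean of at least 5 CPM, plus 1 in the other direction. Outside the lists it takes up to 8 genes per direction with at least 10 CPM and no overlap between groups. The text gives a selection of the genes that met the rule, and single values of some others are not reported here. Genes named outside it are said to be so.

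The procedure was tested on simulated counts drawn from a single mean per gene pooled over all 13 libraries, with 200 genes changed. Genes were drawn independently, with no other difference between groups and no library that departs from its group. The simulation therefore does not show how the tests behave with correlated genes or with such libraries. For the PN comparison (18607 genes) it recovered 2.13% of the 2-fold, 16.3% of the 4-fold, 73.9% of the 16-fold and 88% of the 64-fold changes. For the AAE comparison (18380 genes) these shares were 2.13%, 23.9%, 77.6% and 91.3%. For the difference of effects (18675 genes) they were 0%, 6.25%, 55.1% and 67.3%. For the direct contrast (18666 genes) they were 4.35%, 34.7%, 79.2% and 89.8%, and for the labelled normal brains (18473 genes) 0%, 23.9%, 61.7% and 81.6%. Of all simulated calls, 1.08% to 4.55% were false. A simulated list of 20 genes raised 4-fold in the PN comparison passed with an adjusted p of 1.19e-38 at the preset and 5.77e-06 at the estimated correlation, and none of 33 unshifted lists was called by camera.

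Alternatives listed beforehand were RLE and upper-quartile scaling, other filters, DESeq2 1.42.0, limma-voom, a test against a 2-fold change, fits on fewer libraries, all 5 labelled normal brains as control, and leaving out each library. Further ones were leaving out mitochondrial and haemoglobin genes, limma on log2 of the deposited normalized values plus 1, and other list tests. Added after the data were seen were fits without C2, C5 and AAE5, on protein-coding genes alone, on the genes of the authors' table, with a replicate block, and without genes that share sequence. For the last, 60 words of 31 bases from each of 21904 protein-coding genes were searched in the transcripts of all other genes, with 10% as the limit. Libraries of a group were compared for duplicates, and every pair differed by more than counting noise, with a chi-square per degree of freedom of at least 6.28. Python tables and plots used pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.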

Results

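RNA was sequenced from mouse brain tumours induced with a lentiviral vector for PDGFB and a hairpin against p53, and from brains labelled normal. The design text presents 4 proneural glioblastomas and 2 controls, set beside a re-used mesenchymal series. Proneural and mesenchymal name the glioblastoma expression classes with oligodendrocyte-lineage genes and with matrix, wound and myeloid genes. The count data fall into 4 labelled groups: PN tumours (n = 4), normal brains coded C (n = 2), tumours coded AAE (n = 4) and normal brains coded AAE (n = 3). Totals were 12138725 to 13178511 counts in the PN and C libraries and 6569547 to 18450783 in the AAE libraries. The titles number the libraries within groups without saying that each came from its own animal, so p-values measure the spread between these libraries.

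Trp53, the target of the hairpin (chromosome 11, 69580359 to 69591873, plus strand, GRCm38), was examined first in each library. It stood at 25.9, 28.7, 18.5 and 19.9 CPM in the libraries labelled PN3 to PN6, and at 102 and 90.3 CPM in C2 and C5. In the AAE set it was 8.86, 6.25 and 5.16 CPM in the libraries labelled normal and 6.08, 10.5, 5.08 and 8.83 CPM in AAE6 to AAE9. Within that set the labelled tumours did not differ from the labelled normal brains (log2 change 0.17 ± 0.31 SE, adjusted p = 0.70). Pdgfb (chromosome 15, 79995874 to 80014977, minus strand), the mouse gene for the ligand in the vector, was 19.2 to 47.5 CPM in the PN libraries and 87.1 and 67.4 CPM in C2 and C5. It was 6.30 to 19.3 CPM in the AAE libraries labelled normal and 4.68 to 10.9 CPM in those labelled tumour. The labels do not say whether the vector's PDGFB is a mouse sequence that would be counted here.

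Transcripts of neurons, astrocytes and oligodendrocytes were nearly missing from C2 and C5. Microglia markers were not, with a mean log2(CPM + 1) of 4.364 and 3.905, against 4.338 and 4.409 in AAE3 and AAE4. The median pan-neuronal gene reached 0.0518% (C2) and 0.0985% (C5) of its mean level in AAE3 and AAE4, against 117% to 188% in the PN libraries. Snap25, a synaptic vesicle fusion protein (chromosome 2, 136713453 to 136782428, plus strand), had 0 and 0.283 CPM in C2 and C5 and 1390 to 2313 CPM in the PN libraries. In place of neuronal transcripts, genes of pancreatic acinar cells were abundant. The chymotrypsin precursor Ctrb1 (chromosome 8, 111686519 to 111691010, minus strand) reached 20745 CPM in C2 and 5643 CPM in C5, with no count in any PN library. The mean log2(CPM + 1) of 22 acinar genes was 9.91 in C2 and 7.98 in C5 and at most 0.96 in the other libraries. Of these genes, 21 were at 1 CPM or more in both C2 and C5, 4 in any PN library and 2 in AAE3 or AAE4. Islet genes (3.18 and 3.54) and simple epithelial genes (4.61 and 5.48) were also above the other libraries, which reached at most 0.36 and 2.20. Liver genes were at 3.46 in C2 and 0.67 in C5, against 0.25 to 1.33 elsewhere. Lung (0.77 and 1.74), intestine (1.02 and 1.37) and skin genes (1.70 and 1.78) were also above the other libraries, which reached at most 0.53, 0.29 and 1.455. Kidney (0.79 and 0.95), skeletal muscle (1.01 and 1.40) and lymphoid organ genes (0.83 and 0.85) did not exceed the highest other library (1.17, 1.46 and 1.55). These tissue lists were written after C2 and C5 had been inspected. The authors' normalized table holds the same values for both libraries up to a constant factor.

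A further library departed from its label. In AAE5, labelled normal brain, the median pan-neuronal gene stood at 2.41% of AAE3 and AAE4, beside 1.70% to 2.54% in AAE6 to AAE9. Its expression ranked most like that of AAE9 (Spearman 0.967 across genes) and less like AAE3 (0.812) and AAE4 (0.810). The labelled groups were kept as given, so every direction drawn from C2, C5 or AAE5 is a direction against the library labelled normal brain. The counts for each tumour group against labelled normal brain, and for the 2 tumour groups against each other, were also taken without these 3 libraries, a choice made after seeing the data.

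**Figure D1:**
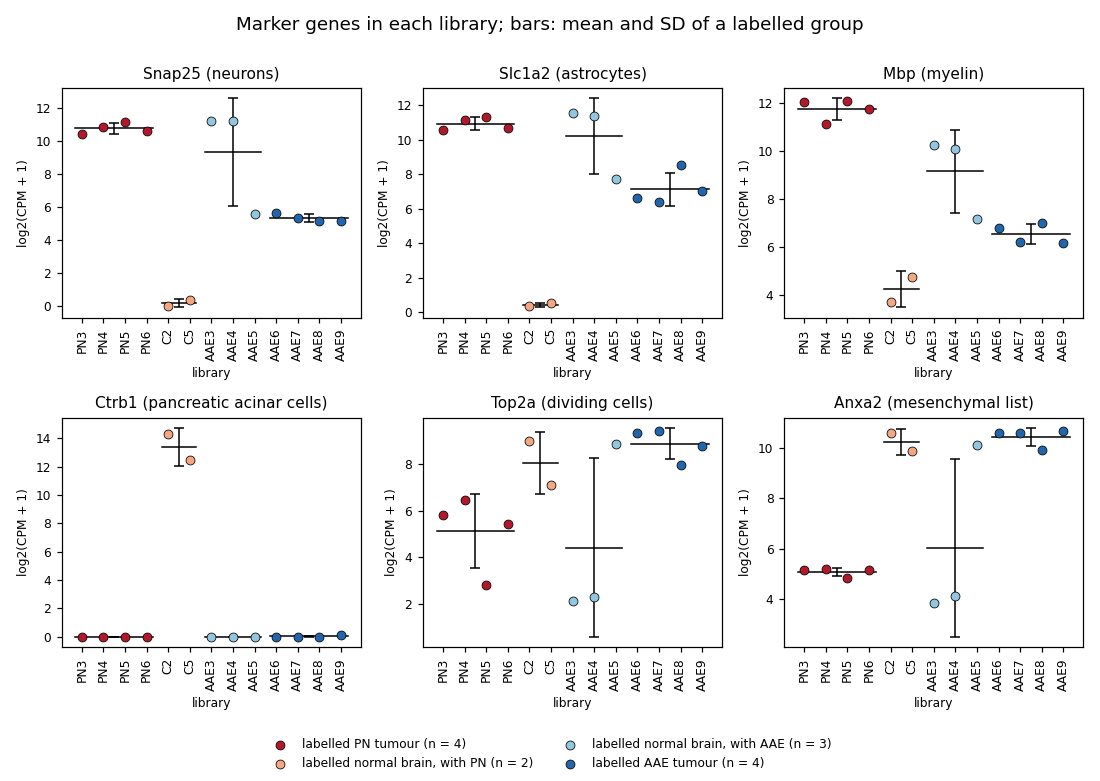
Marker gene levels as log2(CPM + 1) in each of 13 libraries, 1 point per library, with a bar at the mean and a whisker of 1 SD for each labelled group. Snap25 is at 0 and 0.283 CPM in C2 and C5, Ctrb1 is at 20745 and 5643 CPM in them, and Snap25 is at 45.6 CPM in AAE5 and at 33.8 to 49.4 CPM in AAE6 to AAE9.

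The 2 cohorts also differed in transcripts unrelated to tissue. The small nuclear RNA Rn7sk, which lacks a poly(A) tail, took 1.33% to 2.31% of counts in AAE libraries and at most 0.00047% in PN and C libraries. Genes annotated as snRNA, snoRNA or scaRNA took 0.14% to 0.384% in AAE libraries and at most 0.0064% in PN and C libraries. The cohorts thus differ in the kinds of RNA that were counted. Of the protein-coding genes at 5 CPM or more in all 6 PN and C libraries, 50 were at least 8-fold lower in every AAE library, AAE3 and AAE4 included, a pair of limits chosen after seeing the data. They included 24 ribosomal protein genes and Gapdh, a glycolytic enzyme (1245 to 1905 CPM against 9.33 to 31.3 CPM). In the other direction 9 genes met the same rule, all of them histone genes. Any value set across cohorts carries this difference, including Trp53, of whose sampled 31-base words 8.33% also occur in another gene.

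Tumours labelled PN were first compared with C2 and C5, the libraries labelled normal brain that were sequenced beside them. Neuronal, astrocytic and oligodendrocyte genes were higher in the PN libraries than in C2 and C5, and part of the fibroblast, matrix, macrophage and cell cycle genes were lower. In total 8211 of 19859 genes passed, 4977 higher and 3234 lower. The split was 4433 higher and 4454 lower without mitochondrial and haemoglobin genes, 2664 and 3035 without C2, and 3491 and 2091 without C5. All 18 pan-neuronal genes rose, with a median log2 change of 10.67 (10.44 with genes at 0 counts set to their bound), as did 11 of 12 inhibitory neuron genes (10.93, with bounds 9.55). Camera gave adjusted p = 8.18e-14 and 5.00e-07, and both lists had adjusted p = 0.331 with an estimated correlation. Vsnl1, a neuronal calcium sensor, was at least 4550-fold higher in PN (534 ± 105 CPM, SD, n = 4, against 0 counts in both controls). Slc32a1, the vesicular GABA transporter, was at least 922-fold higher (108 ± 19.2 CPM), with 24.9% of its exon bases under exons of the other strand.

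Glial genes followed. Of 15 myelin genes 13 rose and Aspa, an aspartoacylase, fell (median 7.56, adjusted p = 8.71e-09). Of 14 astrocyte genes 12 rose (median 5.76, adjusted p = 3.57e-10), among them Slc1a2, the main glutamate transporter, at 1998 ± 515 CPM against 0.343 ± 0.115 CPM (n = 2). The adjusted p was 0.331 for both with an estimated correlation. Oligodendrocyte precursor genes rose in 13 of 15 cases (median 8.58, with bounds 7.55) and proneural markers in 12 of 18, with 1 that fell (median 6.18, with bounds 5.92). Their adjusted p values were 3.57e-05 and 0.00108, and 0.558 for both with an estimated correlation. Gpr17, a receptor of committed precursors, was at least 548-fold higher and Bcan, a brain proteoglycan, at least 2146-fold higher. Forebrain (9 of 10 rose), striatum (9 of 10) and cerebellum genes (8 of 10) passed with adjusted p values of 5.86e-06, 0.000357 and 0.0021, which became 0.429, 0.367 and 0.367 with an estimated correlation.

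Mesenchymal markers moved the other way, with 10 of 25 lower and 1 higher (median -2.29, adjusted p = 0.000323). The matrix glycoprotein Fn1 had a log2 change of -6.47 ± 0.98 SE and the transcription factor Runx1 -4.52 ± 1.08 SE. The exception was Chil1, a chitinase-like protein (6.51 ± 1.08 SE). Matrix genes (10 of 19 lower, 1 higher), macrophage genes (7 of 16 lower) and cell cycle genes (10 of 24 lower, 1 higher) had medians of -2.33, -2.36 and -2.55. Mural and fibroblast genes fell in 7 of 14 cases and rose in 1 (median -3.32), with the proteoglycans Lum (-7.52 ± 1.14 SE) and Dcn (-5.60 ± 0.64 SE) in front. Adjusted p values for these 4 lists were 0.0012, 0.00433, 0.000324 and 0.000323. With an estimated correlation they were 0.626 for the mesenchymal, matrix, macrophage and cell cycle lists and 0.558 for the mural list. The rotation test fry did not call the mesenchymal, matrix, macrophage and cell cycle lists either (adjusted p = 0.073 for each). Of 15 p53 targets 7 fell (median -0.90, adjusted p = 0.00379, and 0.558 with an estimated correlation). They include Mdm2, the ubiquitin ligase of p53 (-3.19 ± 0.43 SE), and Perp, a desmosome protein also of epithelia (-4.03 ± 0.47 SE). PDGF ligands and receptors fell in 4 of 6 cases (adjusted p = 0.00391, and 0.331 with an estimated correlation), with Pdgfrb at -4.68 ± 0.53 SE. Pdgfb and Trp53 were also lower, by -1.36 ± 0.46 SE (adjusted p = 0.034) and -2.05 ± 0.32 SE (adjusted p = 0.00059). Pdgfra, at -1.67 ± 0.94 SE, and Nf1, at 0.06 ± 0.32 SE, did not pass (adjusted p = 0.17 and 0.92). Adjusted over the list alone, 1 more gene passed in each of the myelin, cerebellum, forebrain and mural lists, and the counts of the 12 other lists named here were unchanged. Dll1, a Notch ligand, was the proneural marker that fell, and Vcan, Ccne1 and Pdpn were the matrix, cell cycle and mural genes that rose. The call of Dll1 ended without PN4 or C5, and that of Vcan without PN3, PN4, PN6, C2 or C5 and with limma-voom.

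Outside the lists the genes that fell most were pancreatic. Ctrb1, the trypsin gene Try5 and the islet and acinar regeneration gene Reg2 had no count in any PN library (at least 39179-fold lower for Reg2). Try5 shares 65% of its sampled words with other genes and is uncertain. Cdc20 (26.7%) and Spp1 (11.7%) also share sampled words with other genes, and 25% and 0% of their words lie at another locus. The calls of Pdgfb, Cd8a, Cdc20, Ccnb2, Ccne1, Spp1 and Pdpn ended when 1 library was left out. They were Pdgfb without PN3, PN4, C2 or C5, Cd8a without PN3, PN6, C2 or C5, Cdc20 without PN3, C2 or C5, Ccnb2 without PN3 or C2, Ccne1 without PN5 or C5, Spp1 without C2, and Pdpn without C2 or C5. Without a filter on low counts the calls of Cdc20, Ccnb2 and Vcan ended, and limma on the authors' table did not call Cd8a. With all 5 labelled normal brains as control 1114 genes passed. Of 36 genes named by rule and called against C2 and C5, 29 lost their call there. Trp53, Pdgfb, Pdgfrb, Fn1, Runx1, Chil1, Perp, Snap25, Vsnl1, Slc32a1, Slc1a2, Aspa, Gpr17 and Bcan were among them, and Pdpn changed sign.

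Set against AAE3 and AAE4 in the fit without C2, C5 and AAE5, the PN libraries gave another picture. There 8005 of 19139 genes passed, 3600 higher and 4405 lower. Of 19096 genes tested in both fits, 1086 were called in the same direction and 1696 in the opposite one. Antigen presentation genes rose in 15 of 15 cases (median 5.11, adjusted p = 9.91e-18), with the invariant chain Cd74 at 8.10 ± 0.63 SE. Interferon genes rose in 20 of 20 (median 4.49, adjusted p = 8.08e-12), lymphocyte genes in 11 of 16 (4.38, adjusted p = 0.00207) and cell cycle genes in 17 of 24, with 1 lower (2.92, adjusted p = 0.000729). The 20 listed lymphocyte genes together summed to 4.02 and 4.43 CPM in AAE3 and AAE4 and 13.8 to 65.9 CPM in PN. Their median change thus rests on values near the floor. Mesenchymal markers rose in 19 of 25 cases with 1 lower (2.11, adjusted p = 1.73e-05), macrophage markers in 10 of 16 with 1 lower (2.50, adjusted p = 0.0305) and microglia markers in 8 of 14 with 2 lower (0.95, adjusted p = 0.0264). With an estimated correlation the adjusted p values of these 7 lists were 0.392, 0.467, 0.619, 0.643, 0.467, 0.619 and 0.467. Red blood cell genes rose beside the lymphocyte and antigen presentation genes, in 4 of 5 cases (4.85, adjusted p = 0.0305, and 0.619 with an estimated correlation). Proneural markers rose in 4 of 18 cases and 1 fell (1.27, adjusted p = 0.0278, and 0.643 with an estimated correlation). Precursor genes (1.07, adjusted p = 0.238) and pan-neuronal genes (0.51, adjusted p = 0.367) did not pass as lists. Nor did p53 targets (5 of 15 higher, 2 lower, 0.26, adjusted p = 0.358) and PDGF genes (1 of 6 higher, 0.14, adjusted p = 0.522), which had fallen against C2 and C5. Cohort and condition coincide in this contrast.

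**Figure D2:**
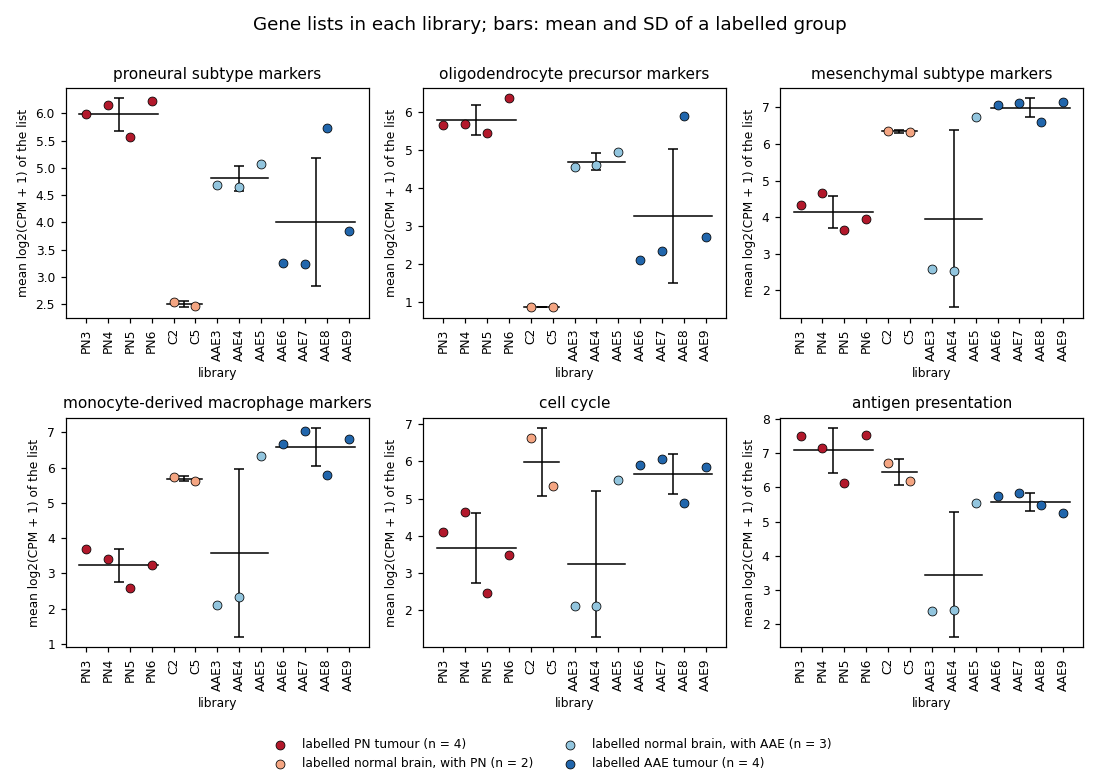
Mean log2(CPM + 1) of 6 gene lists in each of 13 libraries, 1 point per library, with a bar at the mean and a whisker of 1 SD for each labelled group. Mesenchymal markers stand at 2.59 and 2.53 in AAE3 and AAE4 and at 6.60 to 7.16 in AAE6 to AAE9, and AAE8 (5.89) stands apart from AAE6, AAE7 and AAE9 (2.12 to 2.72) in precursor genes.

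Tumours labelled AAE were then compared with the AAE libraries labelled normal. Neuronal and myelin genes were lower in the tumours. Mesenchymal, matrix, macrophage, interferon and cell cycle genes were higher as lists, although few of their members passed singly. In all, 2982 genes passed, 229 higher and 2753 lower. Pan-neuronal genes fell in 14 of 18 cases (median -4.98, adjusted p = 4.45e-08), forebrain genes in 8 of 10 (-5.17, adjusted p = 1.30e-06) and inhibitory neuron genes in 7 of 12 (-3.42, adjusted p = 6.45e-05). Adjusted over the list alone the last 2 lists had 10 and 9 lower genes. Camk2a, a synaptic kinase (12.3 ± 5.42 CPM, n = 4, against 770 ± 664 CPM, n = 3), fell by 5.97 ± 1.01 SE on the log2 scale. Neurod6, a cortical neuron factor, fell by 7.91 ± 1.32 SE. Striatum genes fell in 5 of 10 cases, and in 6 adjusted over the list alone (-3.18, adjusted p = 0.00241). Myelin genes fell in 7 of 15 cases (median -2.08, adjusted p = 0.000136), and in 10, with 1 higher, when adjusted over the list alone. Mbp, a major myelin protein, had a log2 change of -3.10 ± 0.61 SE.

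Mesenchymal markers had a median of 1.61 (adjusted p = 8.27e-09), with Chil1 past the threshold (2.24 ± 0.67 SE). No member passed when adjusted over the list alone. Matrix genes had a median of 1.83 (adjusted p = 4.45e-08), with the basement membrane collagens Col4a1 (2.20 ± 0.67 SE) and Col4a2 (1.86 ± 0.52 SE) past the threshold and 0 of 19 over the list alone. Macrophage, cell cycle and interferon genes had medians of 1.87, 1.58 and 1.66 (adjusted p = 7.52e-06, 2.10e-07 and 8.69e-07) with no member past the threshold. Of the NF-kB genes (2.00, adjusted p = 1.14e-06) Nfkbia, its inhibitor, rose, and of the neutrophil genes (2.01, adjusted p = 0.0012) the gelatinase Mmp9 rose (4.01 ± 1.12 SE). Antigen presentation genes had a median of 1.42 (adjusted p = 7.52e-06) with H2-DMa higher. Mural genes had 1.41 (adjusted p = 6.33e-05) with Col1a1 higher. Neither Nfkbia nor H2-DMa passed when adjusted over the list alone. Hypoxia genes had 0.99 (adjusted p = 0.00425), with Vegfa and Egln3 higher and Car12 lower. Endothelial (1.02, adjusted p = 0.00281) and immune checkpoint genes (1.27, adjusted p = 0.000187) passed with no single member. With an estimated correlation the adjusted p was 0.356 for each list of this comparison named so far.

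Classical markers (0.75, adjusted p = 0.0138), p53 targets (0.64, adjusted p = 0.0111) and chromatin regulators (0.52, adjusted p = 0.0229) also passed upward. Of 14 classical markers 1 rose and 1 fell, and 4 rose and 2 fell when adjusted over the list alone. Zmat3, a p53 target, fell by 1.90 ± 0.45 SE. These lists had adjusted p = 0.356, 0.41 and 0.387 with an estimated correlation. Precursor genes passed downward (adjusted p = 0.0427, and 0.607 with an estimated correlation) with 3 of 15 lower and a mean of -0.67, although their median was 0.26. The rotation test fry called neither the precursor list (adjusted p = 0.165) nor the p53 targets (0.0595). Without AAE8 the precursor median was -3.44. The list did not pass without C2, C5 and AAE5 (adjusted p = 0.383), nor without AAE5, AAE6, AAE7 or AAE9 singly (0.101 to 0.348). Classical markers did not pass without AAE8 (adjusted p = 0.0592). Proneural markers did not pass (0.02, adjusted p = 0.312) but had a median of -1.83 without AAE8. Pdgfb, Pdgfra, Pdgfrb and Nf1 did not pass, with log2 changes of -0.89 ± 0.43, 0.64 ± 0.87, 1.40 ± 0.48 and -0.83 ± 0.28 SE.

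The count of 2982 depended on single libraries. It was 10644 without AAE5, 4477 without AAE8, 506 without AAE3, 507 without AAE4, 654 without AAE6, 587 without AAE7 and 994 without AAE9. The genes higher in the tumours numbered 5097 without AAE5, 836 without AAE8 and 0 to 12 on leaving out 1 of the other 5 AAE libraries. Without PN5 or PN6, which are not compared here but enter the same fit, scaling and filter, the count was 1881 or 1790. A fit on this cohort alone called 0 genes in edgeR (3649 at unadjusted p under 0.05), and limma-voom over all libraries called 0 (8319), while DESeq2 called 5301. Of the 27 named genes that passed, 5 to 19 lost their call on leaving out any PN or C library or AAE3, AAE4, AAE6, AAE7 or AAE9. Upper-quartile scaling ended the calls of Col4a1, Egln3, Vegfa, Nfkbia and H2-DMa, and RLE scaling that of H2-DMa. Testing without a filter ended those of Mmp9, Col4a1 and H2-DMa, a stricter filter that of Nfkbia, and leaving out mitochondrial and haemoglobin genes those of Col4a1, Egln3, Vegfa and Nfkbia.

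In the fit without C2, C5 and AAE5, 11101 genes passed for AAE6 to AAE9 against AAE3 and AAE4, 5315 higher and 5786 lower. Mitochondrial genes took 5.86% and 4.54% of counts in AAE3 and AAE4 and 0.85% to 2.44% in AAE6 to AAE9. Of the 2978 original calls tested in both fits, 2976 were called again in the same direction. Mesenchymal markers rose in 24 of 25 cases (median 5.75, adjusted p = 2.32e-15) and matrix genes in 19 of 19 (4.81, adjusted p = 9.36e-11). Macrophage genes rose in 14 of 16 cases (5.93, adjusted p = 9.45e-08) and cell cycle genes in 22 of 24 (4.80, adjusted p = 1.01e-07). With an estimated correlation the adjusted p values of these 4 lists were 0.144, 0.195, 0.195 and 0.355. The osteopontin gene Spp1 was at 7.60 ± 0.85 SE. Targets of p53 rose in 11 of 15 cases with 1 lower (1.48, adjusted p = 0.0018, and 0.216 with an estimated correlation). Neurons and myelin stayed lower, with 14 of 18 pan-neuronal genes (-5.53, adjusted p = 3.33e-15) and 12 of 15 myelin genes (-2.52, adjusted p = 0.000358) below AAE3 and AAE4 and 1 myelin gene above. These p values became 0.144 and 0.309 with an estimated correlation.

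**Figure D3:**
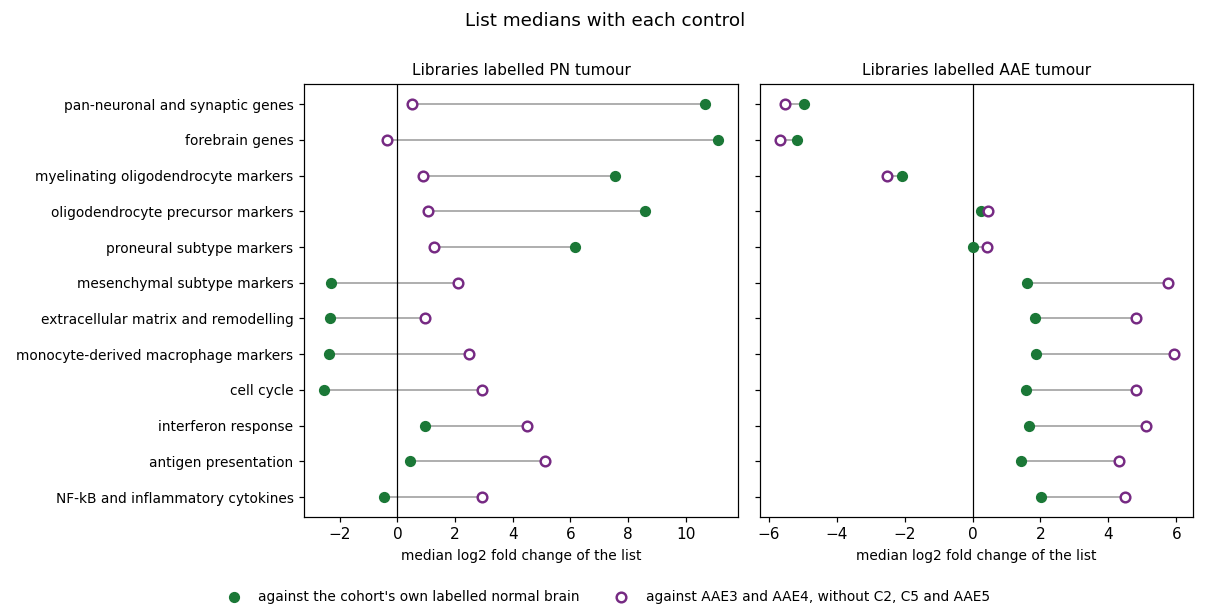
Median log2 fold change of 12 gene lists for the PN tumours (left) and the AAE tumours (right), against the cohort's own labelled normal brain (filled) and against AAE3 and AAE4 in the fit without C2, C5 and AAE5 (open). For the PN tumours the pan-neuronal median goes from 10.67 to 0.51 and the mesenchymal median from -2.29 to 2.11, and for the AAE tumours the mesenchymal median goes from 1.61 to 5.75.

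The difference of the 2 tumour effects asked whether PN and AAE tumours depart from their own labelled normal brain in different ways. Pan-neuronal, myelin and precursor genes changed upward as lists in PN relative to AAE, and mesenchymal and cell cycle genes changed downward. In total 9726 genes passed, 5697 positive and 4029 negative. The split was 5117 and 5002 without mitochondrial and haemoglobin genes, 5207 and 4650 with upper-quartile scaling, and 4641 and 4451 without PN5. All 18 pan-neuronal genes passed as positive (median 15.26, adjusted p = 1.33e-12), as did 12 of 15 myelin genes (9.57, adjusted p = 3.22e-08) and 13 of 15 precursor genes (9.38, adjusted p = 2.48e-05). Mesenchymal markers passed as negative in 13 of 25 cases, with 1 positive (-3.96, adjusted p = 5.82e-07), and cell cycle genes in 17 of 24 (-4.30, adjusted p = 1.49e-06). Adjusted over the list alone these were 14 and 23 negative genes, with the first 3 lists unchanged. With an estimated correlation the adjusted p was 0.367 for the first 4 of these lists and 0.424 for the cell cycle. Fn1 (-8.94 ± 1.34 SE), the macrophage mannose receptor Mrc1 (-7.48 ± 1.43 SE) and Trp53 (-2.22 ± 0.45 SE) were negative. Medians and single values here include fitted values of genes with few or no counts in C2 and C5 and are not bounds. Acinar genes at 9.91 and 7.98 in C2 and C5 and a median pan-neuronal level of 2.41% in AAE5 enter this difference directly.

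Across genes the changes of the 2 tumour groups ran against each other (Pearson -0.598, Spearman -0.599 over 19859 genes, which are not independent replicates). Genes higher in PN and lower in AAE numbered 1935, where independent lists would share 690. Genes lower in both numbered 29 against 448, and genes higher in both 9 against 57.4. Genes lower in PN and higher in AAE numbered 100 against 37.3. The PN changes are taken against C2 and C5, which hold almost no neuronal transcripts. These values therefore do not show opposite departures from normal brain. Against AAE3 and AAE4, without C2, C5 and AAE5, mesenchymal medians were 2.11 (PN) and 5.75 (AAE) and cell cycle medians 2.92 and 4.80. Pan-neuronal medians (0.51 and -5.53) and myelin medians (0.87 and -2.52) went apart there.

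The direct contrast of PN with AAE tumours compares no labelled normal brain, although those libraries enter the spread, scaling and filter of the fit. Each tumour group comes from a single cohort. Cohort and tumour class therefore cannot be told apart. In the PN libraries the median pan-neuronal gene was at 117% to 188% of AAE3 and AAE4, and the median astrocyte gene at 105% to 147%. The share of brain tissue in each tumour library was not measured. Higher neuronal and glial genes in PN are therefore not shown to mark the tumour class. Neuronal, myelin and astrocyte genes were higher in PN, and mesenchymal, matrix, macrophage and mural genes lower. In total 11569 genes passed, 5524 higher and 6045 lower, and 13355 without C2, C5 and AAE5. Mesenchymal markers fell in 15 of 25 cases with none higher (median -3.22, adjusted p = 0.00207). Plau, the urokinase gene (chromosome 14, 20836660 to 20843385, plus strand), was 5.84 ± 1.89 CPM in PN and 1324 ± 657 CPM in AAE (log2 change -7.82 ± 1.62 SE). Matrix genes fell in 17 of 19 cases (-3.94, adjusted p = 0.000122), led by the glycoprotein Tnc (-6.70 ± 1.64 SE). Mural genes fell in 13 of 14 (-3.68, adjusted p = 0.00132), macrophage genes in 12 of 16 (-3.09, adjusted p = 0.00331), endothelial genes in 11 of 16 (-1.51, adjusted p = 0.0295) and cell cycle genes in 9 of 24 (-2.07, adjusted p = 0.0126).

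Higher in PN were 14 of 18 pan-neuronal genes (5.06, adjusted p = 3.27e-06), 10 of 12 inhibitory neuron genes (4.63, adjusted p = 0.000117) and 10 of 10 forebrain genes (4.87, adjusted p = 0.000238). Striatum (8 of 10, adjusted p = 0.000524) and cerebellum genes (9 of 10, adjusted p = 0.017) went the same way. Myelin genes rose in 12 of 15 cases with 1 lower, transferrin (Trf), of whose sampled words 80% lie in other genes and 0% at another locus. Their median was 3.23 (adjusted p = 0.000122). Astrocyte genes rose in 8 of 14 (1.62, adjusted p = 0.00696). Precursor genes rose in 5 of 15 with 1 lower (1.49, adjusted p = 0.017) and proneural markers in 4 of 18 with 1 lower (1.24, adjusted p = 0.031). Sox8, a transcription factor of the oligodendrocyte lineage, was at 3.47 ± 0.85 SE. Lymphocyte genes rose in 10 of 17 with 1 lower (2.34, adjusted p = 0.0295), among them Cd8a (3.84 ± 0.97 SE). The 20 listed lymphocyte genes together summed to 13.8 to 65.9 CPM in PN and 8.38 to 12.4 CPM in the AAE tumours. Cd8a was at 0.65 CPM in PN5 and 0.74 CPM in AAE6. Red blood cell genes rose in 5 of 5, although the list did not pass (2.44, adjusted p = 0.0633). Antigen presentation genes rose in 9 of 15 (1.46, adjusted p = 0.031), with Cd74 at 566 ± 203 CPM against 59.4 ± 23.0 CPM. Without C2, C5 and AAE5 the lymphocyte, precursor, proneural and cerebellum lists did not pass (adjusted p = 0.148, 0.0793, 0.0836 and 0.0836), and the other 13 lists did. These 4 lists also did not pass without AAE5 alone (0.0575 to 0.0952). With an estimated correlation the other 13 lists had adjusted p values of 0.0826 to 0.71 in the fit without C2, C5 and AAE5. Without PN6 the lymphocyte, proneural, antigen presentation and endothelial lists did not pass (0.054 to 0.0562), nor without AAE8 the lymphocyte and antigen presentation lists (0.0603 and 0.0823). Every list passing in this contrast had adjusted p = 0.689 with an estimated correlation, and fry did not call the cell cycle and antigen presentation lists (adjusted p = 0.0589 for both). Adjusted over the list alone, 2 cell cycle genes fell, 14 macrophage genes fell, and 10 astrocyte and 11 lymphocyte genes rose. Pdgfra, the lower gene of the precursor and proneural lists, did not pass among the proneural markers alone, and the other 12 passing lists kept their counts.

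Among the genes outside the lists were hypothalamic hormones. Avp (vasopressin) was 13.9 to 87.8 CPM, Oxt (oxytocin) 2.42 to 83.6 CPM and Pmch (melanin-concentrating hormone) 24.8 to 271 CPM in the PN libraries, with at most 0.26 CPM elsewhere. Pmch lies under exons of the other strand for 58.1% of its exon bases and is uncertain, and Avp and Oxt share 16.7% and 20% of their sampled words with other genes. Pdgfb (2.00 ± 0.41 SE) and Trp53 (1.61 ± 0.28 SE) were higher in PN, and Pdgfra (-2.25 ± 0.83 SE), Pdgfrb (-1.64 ± 0.44 SE) and Nf1 (-0.88 ± 0.26 SE) were lower. The call of Pdgfra ended without PN3, PN4, PN5 or AAE8. The dividing-cell genes Top2a and Bub1 were lower in PN (-3.40 ± 1.33 and -3.98 ± 1.33 SE). The call of Top2a ended without any single PN or C library or without AAE6, AAE7 or AAE9. The call of Bub1 ended without PN5, PN6 or AAE7. Without a filter on low counts the calls of Nf1, Pdgfra, Bub1 and Top2a ended.

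Between the labelled normal brains of the cohorts 10511 genes passed, 3495 higher and 7016 lower in C2 and C5 than in AAE3 to AAE5. The split was 3568 higher and 4157 lower without C2, and 5416 and 7613 without AAE5. All 18 pan-neuronal genes were lower (median -9.86, with bounds -9.61), with 10 of 10 forebrain genes, 10 of 12 inhibitory neuron genes, 13 of 15 precursor genes, and 13 of 15 myelin and 12 of 14 astrocyte genes lower with 1 higher each. Adjusted p values for these lists were 2.05e-07, 0.00104, 0.0015, 0.00285, 0.0001 and 3.05e-05. Antigen presentation (8 of 15 higher, adjusted p = 0.000338), cell cycle (6 of 24, 1 lower, adjusted p = 0.000845) and mesenchymal genes (6 of 25, 1 lower, adjusted p = 0.00178) passed upward. So did classical markers (7 of 14, 2 lower, adjusted p = 0.0114), PDGF genes (4 of 6, adjusted p = 0.0153), p53 targets (5 of 15, 1 lower, adjusted p = 0.0322), mural genes (4 of 14, 2 lower, adjusted p = 0.0322) and NF-kB genes (1 of 16, adjusted p = 0.0497). Adjusted over the list alone, 5 mesenchymal genes rose, 3 cell cycle genes rose with none lower, 11 inhibitory neuron genes fell and 3 classical markers fell, and the other 10 lists kept their counts. All 14 lists had adjusted p = 0.746 with an estimated correlation, and fry did not call the mesenchymal, mural, cell cycle, p53 target and NF-kB lists (adjusted p = 0.0859, 0.0859, 0.0841, 0.0535 and 0.227). The mural call ended without C2, AAE3 or AAE4 (adjusted p = 0.0725 to 0.0886), the p53 target call without AAE3 or AAE4 (0.0826 and 0.0808), and the NF-kB call without C2, AAE3, AAE4, AAE7, AAE8, PN5 or PN6 (0.0509 to 0.137). Trp53 (3.83 ± 0.37 SE), Pdgfb (2.47 ± 0.51 SE) and Pdgfrb (4.45 ± 0.59 SE) were higher and Nf1 (-1.77 ± 0.36 SE) lower, while Pdgfra did not pass (0.06 ± 1.02 SE). A fit on the 5 labelled normal brains alone called 4582 genes. The call of Nf1 ended in that fit and without C2.

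Sex-linked transcripts also split with the PN group. Xist, transcribed from the inactive X chromosome, was 242 to 586 CPM in the PN libraries, which had no count of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. In C2 and C5 Xist was 0 and 0.141 CPM and Ddx3y 1.66 and 5.80 CPM. AAE3, AAE5 and AAE7 had 115 to 292 CPM of Xist, and AAE4, AAE6, AAE8 and AAE9 had 117 to 209 CPM of Ddx3y.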

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

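The tests of C2 and C5, of AAE5, of opposite-strand overlap and of depth were chosen after the results had been seen, while those of shared sequence and of other splits of the libraries were written before their values. The splits in the fit of all 13 libraries were added after the others had been seen.

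C2 and C5 hold almost no neuronal transcripts and abundant pancreatic ones. An admixture of pancreas RNA into brain RNA would leave a visible share of neuronal transcripts, but the median pan-neuronal gene was at most 0.0985% of AAE3 and AAE4. After an exchange with 2 PN libraries, C2 and C5 would hold PN tumour RNA and the 2 PN libraries left in place should resemble them, but the highest acinar mean log2(CPM + 1) in any PN library was 0.51. Libraries of another tissue under a brain label stay open. The acinar mean in C5, the lower of the pair, lay 7.02 above the highest other library, but that list was written after its genes had been seen there, so the value restates the pattern and is no test of it. The labels give no biological difference that was tested here.

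AAE5, labelled normal brain, stands with the AAE tumours. An exchange with a library labelled AAE tumour would need a partner with neuronal genes, and the highest of those had a median of 2.54% of AAE3 and AAE4. A minor share of tumour in normal brain would keep most neuronal transcripts, and AAE5 kept 2.41%. Tumour tissue under a normal label stays open, since the median pan-neuronal gene of AAE5, 1.16 times its mean over the AAE tumours, is the observation that set AAE5 apart and is no test of it. A normal brain that lost its neurons for another reason was not tested.

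The third pattern is the set of 50 protein-coding genes at least 8-fold lower in every AAE library. Lower depth is argued against, since the deepest AAE library held 18450783 counts and the deepest PN or C library 13178511. Reads lost over genes on the other strand are argued against as the whole cause, since 18% of the genes had 50% or more of their exons overlapped. Other genes had 0.581% (Fisher's exact test, two-sided, p = 2.66e-11). Reads shared with near-identical copies may account for the set. Of the sampled words of its median gene 50.8% were found in another gene, against 1.67% in 12564 other genes. Counting only words found at another locus, these medians were 35% and 0%. A different treatment of multiply mapped reads in the cohorts therefore stays open.

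The 7 AAE libraries were also split in other ways. In the fit of all 13 libraries 2 of 35 splits reached the 2982 genes of the labels, so chance is not excluded there. The other one gave 7783 and set AAE5, AAE6, AAE7 and AAE9 against AAE3, AAE4 and AAE8, which points to a structure of the samples other than the labels. A further library must join AAE3 and AAE4 in such a split. With AAE6, AAE7 or AAE9 in that place the count was 2238, 2169 or 2434. Setting AAE6, AAE7 and AAE9 against AAE3, AAE4, AAE5 and AAE8 gave 2976. AAE8 itself ranked more like AAE5 (Spearman 0.965) than AAE3 or AAE4 (0.828 for each), so the split does not show that it resembles them. In the fit of this cohort alone the labels gave 0 genes, which all 35 splits reach by construction, so that fit says nothing about chance. Its highest other split, AAE5, AAE6, AAE7 and AAE9 against AAE3, AAE4 and AAE8, gave 4613. For the 8 tumours, 1 of 35 splits, the real one, reached its 11122 genes and the highest other split gave 0. Every other split puts libraries of both cohorts into each group, so the cohort difference enters its spread within groups. The real split is also the split between cohorts, so the result says nothing about chance apart from cohort.

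Single libraries stood apart from the other 3 of their tumour group in 32 of 253 measures, where chance gives about 1 in 20 (12.7). Named genes were tested only at a group mean of 1 CPM or more, a limit set after seeing the data. AAE8 had 2.31% Rn7sk (others 1.33% to 1.40%). Its mean log2(CPM + 1) was 6.60 for mesenchymal markers (7.07 to 7.16), 5.89 for precursor genes (2.12 to 2.72), 4.88 for the cell cycle (5.85 to 6.05) and 3.57 for NF-kB genes (4.44 to 4.57). Genes high in AAE8 were Ncan (768 CPM), Olig1 (229 CPM), Bcan (165 CPM), Mlc1 (150.5 CPM), Gpr17 (14.1 CPM), Sox8 (19.0 CPM), Nap1l5 (156 CPM) and Esm1 (339 CPM). Genes low in it were Plau (343 CPM), Plaur (76.9 CPM), Anxa2 (953 CPM) and Adamdec1 (21.7 CPM). AAE9 stood apart in pan-neuronal genes (4.62), Mog (1.62 CPM) and Prl8a9 (89.0 CPM), AAE7 in cerebellum genes (1.36), and AAE6 in Klra4 (211 CPM). PN6 stood apart in Malat1 (0.0372% of counts), endothelial genes (3.55, others 3.74 to 3.75) and Pdgfra (211 CPM). PN4 stood apart in mural genes (3.62, others 3.33 to 3.34) and Ncan (466 CPM), and PN3 in Car12 (8.41 CPM). PN5 did so in Col4a2 (37.6 CPM), Col5a2 (5.73 CPM), Olig1 (186 CPM) and Vsnl1 (691 CPM).

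The tested difference of the 2 tumour effects passed for 9726 genes and 20 lists. List medians on the log2 scale were positive for proneural (7.05), precursor (9.38), myelin (9.57), astrocyte (7.75), pan-neuronal (15.26), inhibitory neuron (15.07), cerebellum (8.66), forebrain (14.66) and striatum genes (9.10). They were negative for mesenchymal (-3.96), classical (-1.83), macrophage (-4.39), neutrophil (-6.26), mural (-5.42), matrix (-4.10), cell cycle (-4.30), p53 target (-1.79), PDGF (-2.29), NF-kB (-2.35) and chromatin regulator genes (-1.33). Positive single genes were Vsnl1 (21.12), Snap25 (18.75), Mog (16.29), Bcan (15.36), Gpr17 (15.15) and Chil1 (4.27). Negative ones were Trp53 (-2.22), Pdgfrb (-6.09), Fn1 (-8.94), Anxa2 (-7.11), Runx1 (-6.91), Plac8 (-8.90), Mrc1 (-7.48), Lum (-8.68), Dcn (-7.02), Ccnb2 (-5.29), Mdm2 (-3.93), Il1b (-5.18), Ezh2 (-3.07), Klra4 (-14.26) and Ankrd1 (-13.92). All of these differences include C2, C5 and AAE5. Vsnl1, Mog, Bcan and Gpr17 had 0 counts in C2 and C5, and Klra4 and Ankrd1 had 0 counts in PN3, PN5 and PN6. Their differences, like those of lists with such genes, are fitted values that depend on the prior count and are not bounds. The calls of the cerebellum and proneural lists ended without AAE5 (adjusted p = 0.0955 and 0.0858) and that of the classical list without AAE8 (0.0532). Those of Chil1, Ccnb2 and Il1b ended without C2, and that of Il1b without a filter on low counts.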

How the results depend on the processing

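The fits without C2, C5 and AAE5, on protein-coding genes, on the genes of the authors' table and without genes that share sequence, and those with a replicate block, were chosen after seeing the data. No pairing was assumed, because no label ties libraries of the same number together and the labelled groups of the 5 comparisons share at most 1 number. Deviations from group means correlated across genes at -0.317 (PN3, AAE3), -0.228 (PN4, AAE4), -0.48 (PN5, AAE5) and 0.0832 (PN5, C5). Pairs of different number gave similar values, -0.246 (PN3, AAE4) and -0.203 (PN4, AAE3), so these correlations do not tell whether equal numbers are paired. With the number as a block in edgeR, the PN count was 0 against all 5 labelled normal brains (1377 at unadjusted p under 0.05; 1114 without the block) and 10231 against AAE3 and AAE4 (8005 without it), with 3 and 1 residual degrees of freedom. In the blocked fit of all 13 libraries, with 2, each of the 5 comparisons had 0 genes (326 to 4027 at unadjusted p under 0.05). Across all alternatives 201 counts of genes or lists stayed within 1.5 times and 32 moved. Of single gene values 8311 kept direction and side of the threshold, 809 lost their call, 12 gained one, 16 moved and 9 reversed. Of list values these numbers were 3081, 150, 96, 93 and 12. The gene and list tallies leave out the fits added after seeing the data and the test against a 2-fold change. They thus omit the fit without C2, C5 and AAE5, where 1696 PN genes were called in the opposite direction and 1086 in the same one. They also include refits without libraries that a comparison does not use, so they do not measure how stable the PN directions are. Where not stated, the cause was not tested. Leaving out C2 or C5 leaves 1 library, assumed to vary like the other groups. Limma on the authors' table covers the PN comparison alone.

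For AAE tumours against their labelled normal brain (2982 genes) the count was 0 in edgeR on that cohort alone (3649 at unadjusted p under 0.05), 0 with limma-voom (8319), 0 with all 5 labelled normal brains as control (4378; 12 lists) and 5301 with DESeq2. It was 11101 without C2, C5 and AAE5. Testing against a 2-fold change, which asks for more, gave 997 there, 5153 for PN against its labelled normal brain and 6905 between tumours. With all 5 labelled normal brains the PN count was 1114, and on those 5 alone the between-cohort count was 4582. Without a filter 22 lists passed between cohorts. An estimated correlation left 0 lists in every comparison, while fry, which asks another question, called 13 to 22.

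Leaving out 1 library gave, for genes and lists, 5582 to 10487 and 16 to 19 (PN), 506 to 10644 and 20 to 22 (AAE; 1881 without PN5, 1790 without PN6), 7868 to 12159 and 19 to 22 (difference), 9933 to 13121 and 13 to 21 (direct), and 7725 to 13029 and 11 to 19 (between cohorts).

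Reversed with all 5 labelled normal brains were, for PN, Slco1a4 (-0.29), Pdpn (-0.69), Vcan (-0.63), Spred1 (-0.28), Rab3c (-0.19) and the checkpoint median (-0.080), and for AAE, Sox9 (-1.002), Col1a1 (-1.17), H2-DMa (-0.20), Gpx3 (-0.67) and the classical (-0.65) and antigen presentation medians (-0.20). Between cohorts the matrix and checkpoint medians turned to 0.20 and 0.044 without a filter and 2.99 and 2.20 without AAE5, and matrix to 0.0051 without C5. The lowest values on leaving out 1 library were -0.63 (matrix) and -0.68 (checkpoints). The AAE precursor median was -0.029 without AAE3, -0.021 without AAE4, -3.44 without AAE8 and at most 0.63. The proneural median was -1.83 without AAE8 and at most 0.42.

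Against TMM, upper-quartile scaling shifted the median of all genes by -0.24 (difference), -0.12 (direct) and 0.12 (between cohorts), and leaving out mitochondrial and haemoglobin genes by -0.28 (difference) and 0.27 (between cohorts). Genes at few counts in C2 and C5 are limited by depth.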

Other observations

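Oligodendrocyte precursor genes divided the AAE libraries, a comparison made after seeing the data. The median gene was at 374% of AAE3 and AAE4 in AAE8 and 175% in AAE5, and at 11.3%, 12.6% and 18.0% in AAE6, AAE7 and AAE9. Astrocyte genes were at 83.8% in AAE8, 38.1% in AAE5 and 16.5% to 23.6% in the others. Proneural markers had a mean log2(CPM + 1) of 5.73 in AAE8 and 5.08 in AAE5, against 3.24 to 3.84 in AAE6, AAE7 and AAE9. The mesenchymal mean stayed between 6.60 and 7.16 in all 5 of these libraries.

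Among the PN libraries PN5 had the lowest cell cycle mean (2.47 against 3.47 to 4.65), with Top2a at 6.05 CPM, and the highest pan-neuronal mean (9.27 against 8.50 to 8.90). Cerebellum genes were at 4.82 and 4.80 in PN3 and PN5 and at 2.58 and 3.08 in PN4 and PN6. Red blood cell genes ranged from 2.55 in PN4 to 5.54 in PN5.

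The distance of pan-neuronal genes between the tumour groups was also looked at after seeing the data. At the median gene AAE3 and AAE4 were below the PN tumours by a share of 10.2% of the log2 distance of the AAE tumours. The value carries no explanation here.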
